A study of Mus musculus with 4 samples.

How the data were processed

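Plasma was taken from C57BL/6 mice, WT or lacking gp49B, 21 days after intravenous LLC cells. Exosomes were precipitated from plasma with ExoQuick, RNA was isolated with a column kit, and libraries were made with the QIAseq miRNA kit, which tags each molecule with a UMI, per the labels' protocols. Sequencing was on an Illumina NextSeq 500, per the labels. There were 4 libraries, 2 per genotype, each from a pool of 3 (WT) or 4 (KO) plasma samples, per the labels.

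The values used were the deposited UMI counts per mature miRNA, whole numbers with no normalization, and the deposited read counts served as an alternative. The authors also deposited a normalized value per library. In those tables the column name of WT pool 2 is that of WT pool 1 and the column name of KO pool 2 also departs from its label. Each was therefore assigned by its label and checked by its UMI counts, which were identical to those of the library so named in the table of all libraries. It equals log2 of the UMI count plus 1 constant per library (-0.0276 in WT pool 1, 0.0296 in KO pool 1, 0.215 in WT pool 2 and -0.209 in KO pool 2), with 0 where the count is 0. The constants nearly cancel within each pool number, as they would if the libraries of each pool number were scaled together and apart from the other pool number. How they were scaled is not given in the sources used here. FastQC 0.11.9 and the build GRCm38/mm10 are named, per the submitters' processing notes, and the aligner and the counting tool are not given in the sources used here.

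Libraries with the same pool number shared a list of features: 1930 in pool 1 (1863 miRNAs and 67 piRNAs) and 1888 in pool 2 (1816 and 72). The smallest count above 0 was 10 in both pool 1 libraries, and 1 in WT pool 2 and 2 in KO pool 2, so a 0 in pool 1 means only that the miRNA is listed at 0. The 1809 miRNAs listed in both were compared, and the 54 listed in pool 1 only, the 7 in pool 2 only and the piRNAs were left out. Total reads were 8506987 in WT pool 1, 5363570 in WT pool 2, 9852162 in KO pool 1 and 7706626 in KO pool 2. Positions on GRCm38 were the deposited loci, available for 1799 of the 1809 miRNAs. Sequences of these were read at those positions from the GENCODE precursor transcripts that cover them.

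Genotypes were compared with edgeR 4.0.16 (R 4.3.3): default filtering by expression, TMM scaling, quasi-likelihood F-test, two-sided, Benjamini-Hochberg adjusted p under 0.05. TMM factors were 1.70 in WT pool 1, 0.574 in WT pool 2, 1.50 in KO pool 1 and 0.684 in KO pool 2, so they differed more by pool number than by genotype. With 2 libraries per genotype the fit has 2 residual degrees of freedom. Lists of miRNAs, 16 in number and fixed before the data were examined, were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, then with an estimated correlation and with fry. The estimated correlation rests on 2 residual degrees of freedom, or 1 with the block. That leaves little power, so not passing with it decides little. Each list's share of miRNA UMIs was compared with a two-sided exact permutation test, which has 6 splits and a smallest p of 0.333. Members of the lists came from textbook knowledge of tissues and clusters.

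The labels do not say that libraries with the same pool number were handled together, so the main comparison has no block. The counts and feature lists do differ by pool number, so KO over WT ratios of TMM-scaled UMIs are given within each pool number, with exact 95% intervals that cover counting error only, and blocked results are given beside the others.

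miRNAs were named by a rule fixed before the data were examined: up to 10 called in each direction, filled to 5 by lowest unadjusted p where fewer passed, all members of the miR-1 and miR-206 family, the 10 most abundant, and up to 4 of each list by lowest p. Names chosen after their values were seen are stated as such. Only some of those named by the lists' part of the rule are given in the text.

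The alternatives were size factors of DESeq2 type, total counts, other filters on low counts, pool number as a block, each library left out, the most abundant miRNA or the red blood cell list left out before scaling, limma-voom, DESeq2 1.42.0, robust estimation, read counts, an adjusted p under 0.1, the authors' log2 values in limma, and other denominators for shares. Scaling on, or testing only, miRNAs with a mean of 100 or more UMIs, each also with the block, and DESeq2 with the block were added after the data were seen, as was a test of pool 2 against pool 1 under 3 scalings. The edgeR test was tested on simulated counts for the same 1797 miRNAs, with 200 changed by known folds, at the fitted dispersion of 0.127 and at the blocked fit's 0.0422. Tables were prepared with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1.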

Results

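Small RNA of exosome preparations precipitated from plasma was sequenced from C57BL/6 mice 21 days after Lewis lung carcinoma (LLC) cells, a transplantable mouse lung tumour line, were given into a vein. Exosomes are small membrane vesicles that cells release, and whether the RNA lay inside them was not checked here. The mice were wild type (WT) or lacked gp49B (gp49B KO), an inhibitory receptor found on myeloid cells. Each genotype was represented by 2 libraries, numbered pool 1 and pool 2, and each library was made from a pool of plasma samples: 3 samples in each WT pool and 4 in each KO pool, so the number of plasma samples pooled followed genotype. The deleted gene encodes a protein and its mRNA was not analysed here, so the genotype labels were not checked against it. Counts of unique molecular identifiers (UMIs), tags that mark single RNA molecules before amplification, totalled 1607218 in WT pool 1, 3179081 in WT pool 2, 1729201 in KO pool 1 and 3645842 in KO pool 2. Pool 1 libraries were read more deeply per molecule than pool 2 libraries, with 5.29 and 5.70 reads per UMI against 1.69 and 2.11. Of 1809 miRNAs listed for all 4 libraries, the middle one had 47 UMIs in WT pool 1, 31 in WT pool 2, 43 in KO pool 1 and 42 in KO pool 2.

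The first comparison asks what the vesicle preparations of the 2 genotypes were made of. The most abundant miRNA by mean over the libraries was miR-16-5p, a miRNA common in blood cells, with 35.4% of miRNA UMIs in WT pool 1 (exact 95% binomial interval 35.3 to 35.5%), 24.8% in WT pool 2, 29.4% in KO pool 1 and 28.5% in KO pool 2. In WT pool 2 it came after miR-122-5p (26.6%), the main miRNA of hepatocytes (chromosome 18, 65248866 to 65248887, plus strand, GRCm38, in an exon of a long noncoding RNA), and the third by mean was miR-486b-5p, which is rich in red blood cells. The 10 miRNAs of the red blood cell list together took 48.9% and 46.0% of UMIs in WT pools 1 and 2, and 39.5% and 49.4% in KO pools 1 and 2. That list holds miR-16-5p, which made up most of its share in each library, so these shares do not measure red blood cells alone. The 7 liver-enriched miRNAs took 11.4% and 27.3% in WT against 7.49% and 20.3% in KO, and thus differed more between pool numbers than between genotypes. The muscle-enriched list took 2.37% and 2.99% in WT against 5.49% and 3.22% in KO, the miR-1 and miR-206 family 0.388% and 0.349% against 3.63% and 0.622%, and the let-7 family 8.54% and 7.93% against 10.5% and 9.18%. In these 3 of 16 lists both KO shares lay above both WT shares, and 33.3% of lists would do so, in either direction, by chance if the libraries were exchangeable. The two-sided exact permutation p was 0.333 for each, the smallest that 2 against 2 libraries allow. The muscle list and the family are not separate, since both hold miR-206-3p, miR-1a-3p and miR-1b-5p. Alone, miR-206-3p took 0.0827% and 0.170% in WT against 1.53% and 0.412% in KO, and miR-1a-3p 0.252% and 0.167% against 1.77% and 0.193%. The muscle list also holds miR-486a-5p of the red blood cell list, with 30080 and 80729 UMIs in WT and 24449 and 91130 in KO. The myeloid list took 4.62% and 2.38% in WT and 8.24% and 2.91% in KO, and the stromal and smooth muscle list 2.59% and 1.59% in WT and 4.19% and 1.81% in KO. Shares on the platelet and endothelial list were 4.92% and 2.69% in WT and 8.46% and 2.94% in KO. Without KO pool 2 the lists with separated shares numbered 14, and without WT pool 1 they numbered 11, without KO pool 1 8 and without WT pool 2 5.

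The main comparison asks which miRNAs differ between gp49B KO and WT. A difference of at least 2-fold in both pools was seen in miR-206-3p, a miRNA of skeletal muscle (UGGAAUGUAAGGAAGUGUGUGG, chromosome 1, 20679055 to 20679076, plus strand, in an exon of the long noncoding RNA Gm28653). It had 26116 UMIs in KO pool 1 against 1305 in WT pool 1, and 14940 in KO pool 2 against 5392 in WT pool 2. In CPM after TMM scaling this was 8093 ± 2933 in KO and 1726 ± 1751 in WT (SD, n = 2 each), a log2 fold change of 2.23 (SE 0.96). Within pools the KO over WT ratio was 20.8 (exact 95% interval 19.7 to 22.1) in pool 1 and 2.03 (1.97 to 2.10) in pool 2. Among 352 miRNAs with a mean of 100 or more UMIs, a limit set after the data were seen, it was the only one at least 2-fold apart in the same direction in both pools with TMM, where 0.355 higher in both would be counted if the pools were unrelated. Scaled on total UMIs, its ratios were 18.5 and 2.42, and miR-203-3p, chosen after its values were seen, also passed 2-fold in both pools (2.19 and 2.04). Of the 1780 miRNAs tested that had counts above 0 in all libraries, 2 were at least 2-fold higher in both pools and 9 at least 2-fold lower, each of the 9 at 139 UMIs or fewer, where 1.93 and 2.02 would be counted if the pools were unrelated. With edgeR's quasi-likelihood test, the unadjusted p of miR-206-3p was 0.042 and its Benjamini-Hochberg adjusted p 0.99995, so the difference did not pass.

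Of the 1797 miRNAs tested, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, with 32 at an unadjusted p under 0.05 (15 higher and 17 lower in KO) where 89.85 would fall by chance. At the same unadjusted threshold limma-voom counted 27 and DESeq2 28, and each also called 0. With pool number as a block the edgeR test called 0, with 78 at an unadjusted p under 0.05 and a lowest adjusted p of 0.790. DESeq2 with the block also called 0, with 19 at an unadjusted p under 0.05. What this comparison could find was limited: on simulated counts for the same 1797 miRNAs, the test found 0% of 2-fold changes, 60.5% of 4-fold changes and 94% of 8-fold changes. With counts simulated at the lower dispersion of the blocked fit, the same unblocked test found 19%, 92% and 99.5%. Both simulations gave all miRNAs 1 dispersion and drew libraries independently, whereas same-numbered libraries deviated alike (correlation across miRNAs 0.527). These rates may be too high for abundant miRNAs, whose standard errors were large. They were 1.26 for miR-16-5p and 0.96 for miR-206-3p, against 0.42 for miR-6943-3p at 105 UMIs or fewer. With pool number as a block the same 3 were 0.21, 0.91 and 0.21. The large value of miR-16-5p thus went with pool number, and that of miR-206-3p did not. Calls appeared under a few other settings: 2 without WT pool 2, 3 without KO pool 2, and, with the block, 18 when scaled on and 10 when restricted to miRNAs with a mean of 100 or more UMIs, the last pair chosen after the data were seen. The blocked fits left 1 residual degree of freedom, and miR-206-3p was called in both (log2 fold change 2.61 in each, SE 0.39 and 0.42). Both also called miR-1a-3p, miR-1b-5p, miR-5112, miR-6956-5p and miR-7673-3p, each at least 2-fold higher in KO in 1 pool only, and some miRNAs lower in KO. Those fits took the residual spread to be alike for all miRNAs, and the blocked fit to all 1797 gave miR-206-3p a similar log2 fold change, 2.70, with an SE of 0.91 and an adjusted p of 0.898.

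**Figure D1:**
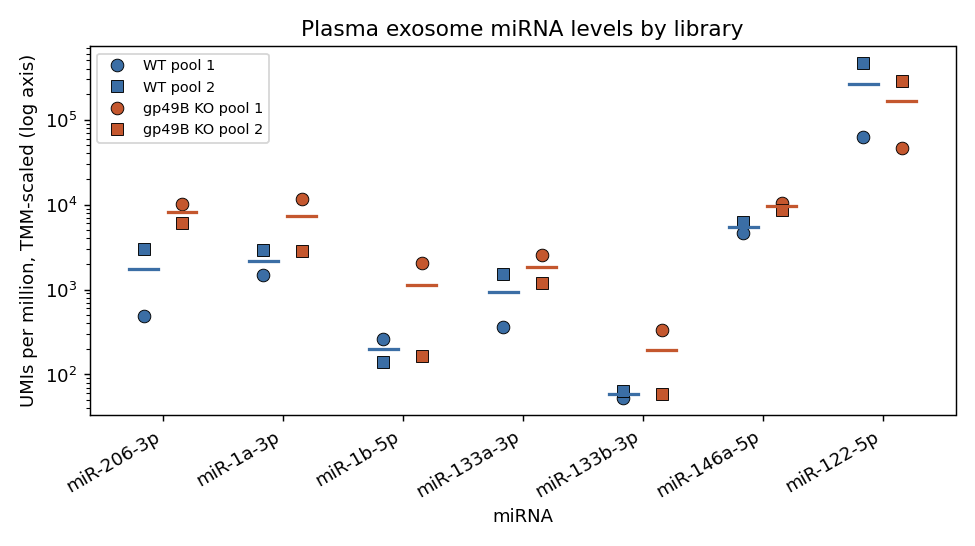
CPM after TMM scaling (log axis) of 7 miRNAs in each of the 4 libraries; circles are pool 1, squares are pool 2, blue is WT, orange is gp49B KO, and each horizontal line is the mean of 2 libraries. With this scaling both KO libraries lie above both WT libraries for miR-206-3p and miR-146a-5p, and for miR-1a-3p, miR-1b-5p, miR-133a-3p and miR-133b-3p KO pool 1 alone does.

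The miR-1 and miR-206 family, chosen because the study is known to have reported it on these samples, is not independent evidence of a direction. Of its 6 tested members, 5 had higher estimates in KO and 0 were called, over all miRNAs or adjusted over the list alone (lowest adjusted p over the list 0.125, edgeR). The cardiac and skeletal muscle miRNA miR-1a-3p (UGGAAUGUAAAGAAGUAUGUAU, chromosome 18, 10785485 to 10785506, minus strand, in an intron of Mir133a-1hg, with a copy on chromosome 2) had 30290 UMIs in KO pool 1 against 3972 in WT pool 1. In pool 2 the counts were 6989 and 5287. Its ratio was 7.94 (7.69 to 8.21) in pool 1 and 0.969 (0.935 to 1.00) in pool 2, and the pool 2 ratio was 1.15 when scaled on total UMIs. For miR-1b-5p (chromosome 18, 10785486 to 10785506, plus strand, in an intron of Mib1) the ratios were 7.93 and 1.19, and for miR-1a-1-5p 5.39 and 0.971, or 1.16 in pool 2 when scaled on total UMIs. By contrast miR-1b-3p, with 65, 20, 62 and 20 UMIs in WT pools 1 and 2 and KO pools 1 and 2, had ratios of 0.994 and 0.733, and miR-206-5p had 1.26 and 2.22. As a list the family rose in KO (camera, preset correlation 0.01, adjusted p = 6.89e-05), with adjusted p = 0.697 with an estimated correlation and a fry adjusted p of 0.925. The estimated correlation, here and for the lists below, rests on 2 residual degrees of freedom, which leaves little power to pass. The preset correlation takes members as nearly independent, but miR-1b-5p is the reverse complement of part of miR-1a-3p and was counted in step with it. The first p and the count of higher estimates may therefore hold the same signal more than 1 time. The list's adjusted p was 0.000248 with pool number as a block and 0.315 without KO pool 1.

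Muscle-enriched miRNAs rose as a list (camera, adjusted p = 0.0174, and adjusted p = 0.697 with an estimated correlation), with 7 of 11 estimates higher in KO. The pools differed: with TMM 9 of 11 were higher in KO in pool 1 but 3 of 11 in pool 2, with median ratios of 1.45 and 0.831. With total UMIs these were 8 and 5 of 11, with medians of 1.29 and 0.990. The list shares miR-1a-3p, miR-1b-5p and miR-206-3p with the family above and miR-486a-5p with the red blood cell list. Outside the family, miR-133b-3p, which lies near miR-206 in the same host transcript, had ratios of 6.34 (5.30 to 7.63) in pool 1 and 0.914 (0.712 to 1.18) in pool 2, or 1.09 in pool 2 when scaled on total UMIs. For miR-133a-3p, looked at after its values were seen, they were 7.02 (6.56 to 7.52) and 0.790 (0.750 to 0.833). The heart miRNAs miR-208a-3p and miR-208b-3p and the muscle miRNA miR-499-5p, also looked at afterwards, had pool 1 ratios of 0.876, 1.11 and 1.26 at 68 UMIs or fewer. The median log2 fold change of the list was 0.23 and its mean 0.77, so a few members carried the difference. The list's adjusted p was 0.0169 with pool number as a block, 0.968 without KO pool 1 and 0.158 without WT pool 1.

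The liver-enriched list fell in KO (camera, adjusted p = 0.0178, and adjusted p = 0.697 with an estimated correlation), and all 7 members had lower estimates, though 0 were called by edgeR. All 7 were lower in KO in both pools with TMM scaling, and 5 of 7 with scaling on total UMIs. Ratios of miR-122-5p were 0.755 (0.749 to 0.760) in pool 1 and 0.620 (0.618 to 0.622) in pool 2, and those of miR-192-3p 0.446 (0.303 to 0.647) and 0.804 (0.590 to 1.10). For miR-802-5p they were 0.598 and 0.909, for miR-802-3p 0.748 and 0.762, and for miR-122-3p 0.533 and 0.905, and with scaling on total UMIs the pool 2 ratios of miR-802-5p and miR-122-3p were 1.08 each. The median log2 fold change of the list was -0.44. The list's adjusted p was 0.000895 with pool number as a block, 0.884 without KO pool 1 and 0.458 without WT pool 2.

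The list of the Dlk1-Dio3 cluster, an imprinted cluster on chromosome 12, with 34 of its miRNAs but not miR-136-3p or miR-679-5p, rose as a list (camera, adjusted p = 0.0174, and adjusted p = 0.697 with an estimated correlation). Estimates were higher in KO for 20 of 34 members and lower for 14, with 18 higher and 7 lower in both pools and a median log2 fold change of 0.22. Members of the list with the lowest unadjusted p were miR-136-5p, with 30, 25, 47 and 111 UMIs in WT pools 1 and 2 and KO pools 1 and 2, miR-377-3p with 20, 5, 29 and 34, miR-411-5p with 36, 42, 81 and 85, and miR-379-5p with 333, 397, 851 and 687. The last had ratios of 2.66 (2.34 to 3.03) and 1.27 (1.12 to 1.44), and none of the 4 passed the edgeR test. The list's adjusted p was 0.00165 with pool number as a block, 0.767 without WT pool 1, 0.395 without KO pool 2 and 0.0764 without KO pool 1.

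The 12 other lists did not pass. All 9 myeloid miRNAs had higher estimates in KO (camera, adjusted p = 0.0595; 0.697 with an estimated correlation), and with pool number as a block the list passed (adjusted p = 0.00547, and adjusted p = 0.656 with the block and an estimated correlation). The neutrophil and monocyte miRNA miR-223-3p had ratios of 2.79 (2.75 to 2.83) in pool 1 and 0.717 (0.704 to 0.731) in pool 2, and miR-146a-5p, which is induced by inflammatory signals, had 2.23 (2.18 to 2.28) and 1.41 (1.38 to 1.44). Ratios of miR-146b-5p were 3.43 and 0.861, and those of miR-223-5p 1.96 and 0.923, or 1.03 and 1.10 in pool 2 when scaled on total UMIs. In pool 2, 4 of the 9 were higher in KO with TMM and 8 of 9 with total UMIs. On the platelet and endothelial list (adjusted p = 0.0595) 3 of 7 were higher in KO in both pools, or 4 with total UMIs, and 4 of 7 were lower in pool 2. The 3 were miR-199a-3p, counted together with miR-199b-3p, at 1.69 and 1.57, miR-199a-5p at 2.87 and 1.24, and miR-24-3p at 1.69 and 1.25, and the list also holds miR-223-3p. With the block 8 lists passed in place of 4, the additional ones being platelet and endothelial (0.00729), stromal and smooth muscle (0.0107) and miR-200 family (0.0234) besides myeloid. With an estimated correlation 0 lists passed with the block, and the adjusted p was 0.656 for each of these. Without the block these had adjusted p of 0.0595, 0.0947 and 0.104 with the preset correlation. The blocked estimate rests on 1 residual degree of freedom and was 1 for the platelet and endothelial list, so not passing with it decides nothing. On the stromal list 9 of 10 were higher in KO in pool 1 but 3 of 10 in pool 2 with TMM, with median ratios of 1.77 and 0.840. With total UMIs these were 9 and 5 of 10, with medians of 1.57 and 1.00. The stromal list shares miR-199a-5p and miR-199a-3p (counted with miR-199b-3p) with the platelet and endothelial list. They were the 2 stromal members higher in KO in both pools with TMM, so the passes of these lists with the block are not separate. In the stromal list miR-145a-5p, a miRNA of smooth muscle, had ratios of 1.82 and 0.479 with TMM. The remaining lists were neural (0.164), let-7 family (0.271), Sfmbt2 cluster (0.271), lymphocyte (0.358), red blood cell (0.682), miR-17/92 cluster (0.693), tumour and metastasis-associated (0.723) and pancreas-enriched (0.895). On the neural list 7 of 8 estimates were lower, including miR-9-5p, with ratios of 0.800 and 0.408, and miR-9-3p, with 0.889 and 0.415. In the red blood cell list miR-144-3p had ratios of 0.441 and 1.09.

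By lowest unadjusted p, the miRNAs with lower estimates in KO were all counted at low levels. They were miR-6943-3p, with 105, 69, 31 and 31 UMIs in WT pools 1 and 2 and KO pools 1 and 2, miR-470-3p with 62, 25, 16 and 13, miR-3098-3p with 46, 48, 10 and 23, miR-302a-3p with 59, 52, 32 and 18, and miR-497a-3p with 53, 61, 25 and 28. Of these miR-6943-3p, encoded in an intron of Grk6 (chromosome 13, 55453150 to 55453171), had the lowest unadjusted p, 0.00239, at a log2 fold change of -1.65 (SE 0.42) and ratios of 0.308 (0.199 to 0.463) and 0.329 (0.208 to 0.510), with an edgeR adjusted p of 0.99995. Ratios were 0.269 and 0.381 for miR-470-3p, 0.226 and 0.351 for miR-3098-3p, 0.565 and 0.254 for miR-302a-3p and 0.491 and 0.336 for miR-497a-3p. Higher estimates by the same rule were those of miR-679-5p, miR-136-5p, miR-136-3p, miR-5112 and miR-1b-5p. For miR-679-5p (chromosome 12, 109715587 to 109715608, in the Dlk1-Dio3 cluster) the counts were 0, 5, 18 and 21, and the pool 1 tables hold no value from 1 to 9, so no ratio is given for pool 1. For miR-136-3p, the other arm of miR-136, they were 25, 23, 45 and 75, and for miR-5112 35, 54, 32 and 603. The ratio of miR-5112 was thus 0.952 (0.571 to 1.58) in pool 1 and 8.18 in pool 2.

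Among the 10 most abundant miRNAs, log2 fold changes without a block ranged from -0.65 for miR-122-5p to 0.68 for miR-223-3p, each smaller than its standard error. Estimates were -0.06 for miR-16-5p, -0.30 for miR-486b-5p, -0.27 for miR-486a-5p, -0.04 for let-7i-5p, -0.13 for miR-25-3p and -0.22 for miR-93-5p, and 0.22 for let-7b-5p and 0.06 for let-7c-5p. With pool number as a block the standard errors were smaller, and some estimates exceeded theirs while others did not. They were -0.55 (SE 0.22) for miR-122-5p, 0.39 (SE 0.30) for let-7b-5p, 0.50 (SE 0.52) for miR-223-3p and -0.07 (SE 0.21) for miR-16-5p, and none was called. The mature sequences annotated for miR-486a-5p and miR-486b-5p are the same (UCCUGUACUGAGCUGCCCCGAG), so how their counts were divided is uncertain, and let-7 members differ by few bases.

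**Figure D2:**
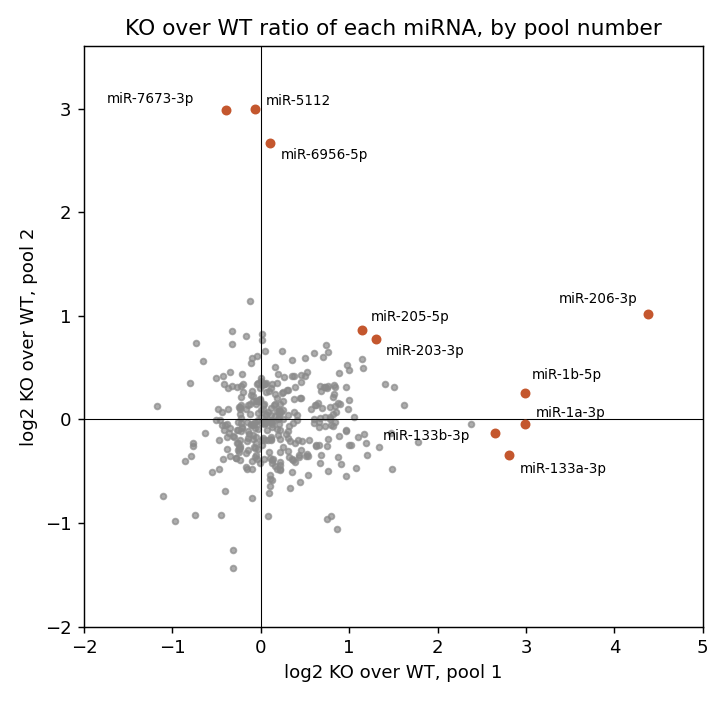
Log2 ratio of KO over WT in pool 1 (horizontal axis) against pool 2 (vertical axis) for the 352 miRNAs with a mean of 100 or more UMIs, each point 1 miRNA, with 10 named miRNAs in orange. The ratios of the 2 pools showed little relation across miRNAs (Pearson's r = 0.0713), and miR-206-3p lies at 4.38 in pool 1 and 1.02 in pool 2.

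Ratios of KO over WT in the 2 pools showed little relation across the 352 more abundant miRNAs (Pearson's r = 0.0713, Spearman's rho = 0.0712), which are not independent replicates, and 52.8% of them had the same direction. At least 2-fold higher in KO were 25 of the 352 in pool 1, among them miR-223-3p, miR-199a-5p and miR-146b-5p, and 5 in pool 2. At least 2-fold lower were 2 in pool 1 and 3 in pool 2. Of the 1797 miRNAs tested, both KO libraries lay above both WT libraries in 171 and below them in 208, together 21.1%. Chance gives 33.3% only for exchangeable libraries, and same-numbered libraries deviated alike (correlation across miRNAs 0.527), which lowers that share.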

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

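All tests of the patterns weighed here were chosen after the result was seen. PiRNAs, which no comparison used, had 28710 UMIs in WT pool 1, 8827 in WT pool 2, 18873 in KO pool 1 and 15505 in KO pool 2, above the limit that a count of 0 allows. These were 1.79%, 0.278%, 1.09% and 0.425% of UMIs. The miRNAs listed for 1 pool number only, also not used, had 759 UMIs in WT pool 1 and 659 in KO pool 1, and 35 in WT pool 2 and 88 in KO pool 2.

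The first pattern is the miR-1 and miR-206 family in the KO library of pool 1, where miR-206-3p was 20.8 times and miR-1a-3p 7.94 times the WT level. Counting error is far too small, since the lower 95% bound of the miR-206-3p ratio was 19.72. RNA from skeletal muscle may contribute in pool 1, where miR-133a-3p and miR-133b-3p, the muscle-list members outside the family and the red blood cell list with a mean of 100 or more UMIs, had a median ratio of 6.68, while the rarer arms miR-133a-5p and miR-133b-5p, at 68 UMIs or fewer, had 1.45 (0.940 to 2.27) and 1.16 (0.665 to 2.02). The annotated sequences of miR-133a-3p and miR-133b-3p differ only in the last base, so how their counts were divided is uncertain. On chromosome 18 miR-133a-3p shares the host transcript Mir133a-1hg with miR-1a-3p, and miR-133b-3p shares Gm28653 with miR-206-3p. Their rise is therefore not independent of the family and cannot decide the source. Whether it contributes in pool 2 stays open: the highest upper bound among miR-1a-3p, miR-133a-3p and miR-133b-3p was 1.176 and the lower bound of miR-206-3p was 1.97, but these cover counting error only and the proportions of these miRNAs in such RNA are not known here. The genotype, untested apart from this, and the make-up of single pools cannot be told apart, since the ratio of miR-1a-3p was 8.2 times as high in pool 1 as in pool 2 and each pool number holds 1 library per genotype.

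The second pattern is that miR-1b-5p, the exact reverse complement of 21 nt of miR-1a-3p, was counted in step with it, at 17.6% of its count in both pool 1 libraries and at 4.82% and 5.94% in WT and KO pool 2. Molecules of miR-1a-3p counted on the opposite strand, more often in pool 1, are a candidate explanation: in 4 other opposite-strand pairs, of which 2 come from the arms of miR-126, the ratio was 2.39 to 4.03 times as high in pool 1 as in pool 2, against 3.30 for miR-1b-5p. Random draws kept the more abundant miRNA of each pair and replaced the rarer one with a miRNA of like abundance. A share of 0.0004 of these draws had as large a median. Between KO and WT the 4 ratios differed by a median of 0.240 on the log2 scale, against 0.407 in such draws, and a share of 0.0955 of draws was as small, which settles nothing. The 2 pairs of miR-486a and miR-486b were left out, since their 5p sequence is the same, and with them the latter share was 0.0124, while single pairs had a KO ratio of 0.589 to 1.59 times the WT ratio. A separate miR-1b hairpin stays open, since its other arm, miR-1b-3p, had a pool 1 ratio of 0.9936 but at 65 UMIs or fewer.

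The third pattern is that 77.6 to 79.0% of miRNAs had 10 to 100 UMIs in each library. Counts that do not come from the named miRNA may contribute: 46 miRNAs of clusters restricted to embryonic stem cells or testis had medians of 42, 20.5, 28.5 and 26 UMIs in WT pools 1 and 2 and KO pools 1 and 2, above the lower quartile of all miRNAs by a factor of at least 1.083. That margin is narrow, since the testis cluster alone had a median of 21 in KO pool 2, under the quartile of 24, and true expression of these clusters was not excluded. Depth stays open, since median UMIs in pool 2 were 0.660 (WT) and 0.9767 (KO) times those in pool 1, against total UMIs of 1.98 and 2.11 times but in the direction of total reads, at 0.630 and 0.782 times. No biological explanation was tested for this pattern, which holds in both genotypes.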

How the results depend on the processing

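The settings based on miRNAs with a mean of 100 or more UMIs, and DESeq2 with the block, were chosen after the data were seen. In the 17 settings that kept all libraries, 740 of 740 log2 fold changes of the 46 named miRNAs kept their direction, and 16 passed the threshold newly. List directions were kept in 189 of 191 values over 12 settings. The exceptions were the pancreas list with total counts only (adjusted p 0.809) and the tumour list with the block when only miRNAs with 100 or more UMIs were tested (0.981). The number of miRNAs called, 0, became 18 with the block when scaled on miRNAs with 100 or more UMIs and 10 with the block when only those were tested. It ranged from 0 to 3 without single libraries, where all 5 called miRNAs were at 0 in 1 pool 1 library (miR-129-1-3p and miR-758-5p without WT pool 2, and miR-1931, miR-493-5p and miR-1946a without KO pool 2). Lists passing, 4, became 9 with total counts only, 8 with pool number as a block, 0 with an estimated correlation, 8 when scaled on miRNAs with 100 or more UMIs, 8 with the block added, 8 when only those were tested, 6 without the red blood cell list (myeloid and platelet and endothelial newly), and 0 to 5 without single libraries. Lists with separated shares, 3, ranged from 5 to 14 without single libraries, where fewer libraries make separation easier. Scaling on miRNAs with 100 or more UMIs moved the median log2 fold change to -0.13, against -0.03 with TMM. Apart from what is stated, the cause was not tested.

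Without single libraries, where the lone library of a genotype is assumed to vary like the other genotype, 15 named miRNAs and 8 lists turned. These fits had no block and set 1 pool number against both, so a turn can reflect pool number and not an unstable genotype difference. Among those that turned, miR-122-5p was lower in KO within both pools (ratios 0.755 and 0.620), while miR-223-3p differed in direction (2.79 and 0.717). Log2 fold changes ranged from -0.25 to 3.37 for miR-1b-5p, -1.14 to 0.57 for miR-1b-3p, -0.76 to 3.53 for miR-5112, -0.71 to 0.56 for miR-16-5p, -2.49 to 1.43 for miR-122-5p, -1.94 to 1.39 for miR-486b-5p, -1.55 to 1.04 for miR-486a-5p, -0.37 to 1.32 for let-7b-5p, -0.63 to 1.58 for let-7c-5p, -0.69 to 0.58 for let-7i-5p, -1.23 to 0.72 for miR-25-3p, -1.29 to 0.69 for miR-93-5p, -0.27 to 1.26 for miR-223-3p, -0.021 to 1.63 for miR-146b-5p and -1.29 to 1.17 for miR-145a-5p. That of miR-206-3p stayed positive, from 1.47 to 4.05. Adjusted p ranged from 0.0764 to 0.949 for the Sfmbt2 list, 0.0758 to 0.904 for let-7, 0.0554 to 0.698 for lymphocyte, 0.130 to 0.597 for miR-17/92, 0.395 to 0.608 for pancreas, 0.0405 to 0.429 for red blood cell, 0.0080 to 0.698 for stromal and 0.467 to 0.919 for tumour.

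Same-numbered libraries deviated from their genotype means alike, with a correlation across miRNAs of 0.527, and the block lowered the dispersion from 0.127 to 0.0422, though the labels pair no libraries. The authors' values were already log2 with 0 at count 0, so limma was run on them with the block (0 called, 79 at an unadjusted p under 0.05) and the versions with added pseudocounts were not run. The red blood cell list was not tested where it was left out.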

Other observations

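Every test here was chosen after the result was seen. Pool number went with more calls than genotype, but which miRNAs were higher depended on scaling. In edgeR's quasi-likelihood test of pool 2 against pool 1, 131 miRNAs were higher and 80 lower in pool 2 at an adjusted p under 0.05 with TMM, 8 and 1386 with total UMIs, and 52 and 372 with scaling on miRNAs with 100 or more UMIs. The liver miRNA miR-122-5p was higher in pool 2 under these 3 scalings, by log2 fold changes of 2.78 (adjusted p = 0.00357), 1.40 (0.000426) and 2.26 (0.00194), and miR-486b-5p, a red blood cell miRNA, by 2.41 (0.00357), 1.05 (0.00306) and 1.90 (0.00249). For miR-106b-3p the values were 2.49 (0.00453), 1.12 (0.00669) and 1.98 (0.0018), and for miR-6377 -2.33 (0.00357), -3.67 (4.8e-07) and -2.83 (0.000248). The red blood cell miRNA miR-451a differed by 1.88 (0.00916), 0.52 (0.168) and 1.37 (0.0103), so it did not pass with total UMIs. That of miR-16-5p changed sign, at 1.07 (0.0295), -0.28 (0.327) and 0.56 (0.198). With TMM, the first principal component, with 60.5% of the variance, held the pool 1 libraries at -15.5 and -13.9 and the pool 2 libraries at 15.1 and 14.3.

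The skin epithelial miRNAs miR-205-5p and miR-203-3p were higher in KO within both pools, with ratios of 2.21 (exact 95% interval 2.13 to 2.29) and 1.82 (1.76 to 1.88) for miR-205-5p and 2.47 (2.37 to 2.58) and 1.71 (1.62 to 1.82) for miR-203-3p. Neither passed the edgeR test, with unadjusted p of 0.219 and 0.141, or 0.0141 and 0.0166 with pool number as a block. A list of 6 skin epithelial miRNAs, written after these values were seen, had 4 higher and 2 lower estimates and an unadjusted camera p of 0.323. The embryonic stem cell clusters miR-290 and miR-302 had 9 higher and 11 lower (0.790), and the X-linked testis cluster 9 higher and 17 lower (0.0532).

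In KO pool 2 alone, miR-5112, miR-6956-5p and miR-7673-3p stood apart, the last pair chosen after their values were seen. Their UMIs were 603, 670 and 382 there, against 54, 76 and 34 in WT pool 2, 32, 55 and 47 in KO pool 1, and 35, 53 and 65 in WT pool 1.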
